A study of Mus musculus with 6 samples.

How the data were processed

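Total RNA from presomitic mesoderm of mouse embryos at embryonic day 10.5 was converted into digoxigenin-labelled cRNA by reverse transcription and in vitro transcription and hybridised to Applied Biosystems one-colour arrays, per the labels' protocols. The sample descriptions name a human array, whereas the organism is given as mouse and the probe annotation used here is that of a mouse array. The deposited values are probe intensities on a linear scale. They had been scaled so that each array's median lies just under 1, and they contain 0 missing values and 0 values at or below 0. The scaling software, background correction, flags and filters are not given in the sources used here. The spread had not been equalised: the ratio of the 75th to the 10th percentile was 42.7 and 56.9 on the replicate 1 arrays of wild type and knockout, and 12.4 to 16.0 on the other 4 arrays. Scaling to a common median leaves such differences of range in the values, and any background handling by the authors affects dim probes most.

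All 6 arrays were used, 3 wild type and 3 Nrarp knockout, grouped by the labels. Of 33012 probes, 14411 had 1 gene in the annotation table, 247 had several and 18354 were unnamed here. The named probes cover 13840 genes, and 540 of these have more than 1 probe, of which the probe with the highest mean log2 intensity was used. Of the named probes, 9 had an Entrez identifier without an entry in the reference gene table (assembly GRCm38.p6, used for names and neighbourhood only), and 0 symbols needed updating. Probes with several genes were tested but not named. The authors' intensities were converted to log2 without further normalization, offset or filter. Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit on genotype, eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Residual degrees of freedom were 4 without and 2 with a replicate block, and prior degrees of freedom were 3.66 and 6.64. Intervals of 95% come from the blocked fit. Single genes were also tested with an exact permutation test, which cannot go below 0.1 with 3 against 3 arrays. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

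The replicate numbers occur in both genotypes, and whether they pair arrays was checked before the fits' calls were compared. Deviations from the group means correlated within number by 0.757, 0.442 and 0.374 over all probes, so the numbers were treated as pairing the arrays. The correlations across numbers 2 and 3 were 0.397 and 0.419, so the pairing comes from the separation of replicate 1 and not from each number. Signs given within pairs 2 and 3 therefore rest on matching by number only, and a match across these numbers can give another sign. The pairing rests on the data, as the labels call the wild-type mice littermates but tie no replicate number to a litter, batch or day.

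The 26 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists cover Notch pathway components, Notch targets, cyclic genes of the Notch and FGF and of the Wnt branches, Wnt targets, FGF signalling, posterior and anterior presomitic mesoderm, Hox genes in 2 groups, axial length regulators, retinoic acid, glycolysis, cell cycle, 9 sets of markers of other cell types, immediate early and heat shock genes, sex-linked controls and the genes next to Nrarp. Lists were tested with limma's camera (inter-gene correlation 0.01, 1 probe per gene), with an estimated correlation, by ranks and with fry. The fry test was run without the intensity trend. Named genes are a fixed set of Notch, clock and presomitic genes, up to 10 genes in each direction that pass with separated groups and above the median level, filled up to 5 by the smallest unadjusted p where fewer pass, and in each list up to 4 members that pass or the 2 with the smallest p.

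The fits were tested on simulated data for the comparison of knockout with wild type, with 33012 probes, 200 of them seeded with changes, in 20 runs. Seeded probes were drawn only from those above the median level, and the simulated data held the fitted replicate effects. The recovered shares therefore do not cover dimmer probes or data in which the replicate numbers do not pair the arrays. The spread was taken either from each probe's posterior estimate or, in a simulation added after the first one gave more false calls than the nominal 5%, drawn from the fitted prior, and the number of runs was then raised from 5. The fit without the block recovered 0% of 2-fold changes under both, and 0.20% and 0.15% of 4-fold changes. With the posterior spread the blocked fit recovered 54.3% of 2-fold and 89.4% of 4-fold changes, and 9.51% of its calls were false (4.26% to 16.1% in single runs). With the prior spread it recovered 27.9% and 65.1%, and 5.97% of its calls were false (1.11% to 9.18%). With 0 seeded changes the blocked fit called at least 1 probe in 12 of 20 runs with the posterior spread, at least 2 in 8 of them and at most 4, and in 3 of 20 runs with the prior spread, where the most was 1. The fit without the block called 0 in these runs. The alternatives were other normalizations between arrays, an offset of 0.286 before log2, filters on dim probes, other variance models, array weights, the replicate block, averaging the probes of a gene, leaving out each array and other thresholds and set tests. A batch term for replicate 1, replicates 2 and 3 alone, and combinations with the block were added after the data were seen.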

Results

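Gene expression was measured in presomitic mesoderm, the unsegmented tissue at the tail end of the embryo from which somites bud, of mouse embryos at embryonic day 10.5. Littermate wild-type embryos were compared with embryos in which the coding region of Nrarp had been replaced by LacZ. Nrarp encodes a small ankyrin-repeat protein that is induced by Notch signalling and acts back on it. The series asks how Notch signalling bears on the period of the segmentation clock and on the number of vertebrae. Each genotype had 3 one-colour arrays, numbered 1 to 3, each with 33012 probes, and 12 presomitic mesoderms had been collected per genotype. How the tissue was divided among the arrays was not stated, so p-values measure only the spread between these samples, which may be technical. Intensities had been scaled so that array medians lay between 0.981 and 0.993, and array sums lay between 1019520 and 1125059. The small number of arrays limits the precision of every value given here.

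The Nrarp probe (919347) was bright in wild-type tissue and far lower in knockout tissue. Its scaled intensity was 398 ± 70.2 (SD, n = 3) in wild type and 26.7 ± 14.4 (SD, n = 3) in the knockout. The single arrays read 318, 429 and 448 in wild type against 14.3, 42.5 and 23.3 in the knockout. The knockout readings still lay above the 75th percentiles of their arrays (9.71, 4.90 and 5.43), so a signal remained. The log2 difference was -4.03, which leaves 6.14% of the wild-type signal. In the limma fit without a replicate term the adjusted p over all probes was 0.428. With the replicate number as a block it was 0.00042 (log2 SE 0.197), and the fold was 16.3 (95% interval 11.9 to 22.2). Within replicate 1 the log2 difference was -4.48, and within replicates 2 and 3 it was -3.80 (limma adjusted p = 0.00167). The exact permutation test of the 3 against 3 values gave p = 0.1 (two-sided), the smallest that this design allows. Whether the probe lies inside the replaced part of the gene was not given in the sources used here, so the drop is a check of the labels only if it does.

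Hes5, a basic helix-loop-helix repressor that is a direct target of Notch in many tissues, was higher in every knockout array than in any wild-type array. Its intensity was 9.57 ± 1.36 (SD, n = 3) in wild type and 40.9 ± 8.45 (SD, n = 3) in the knockout. The log2 difference was 2.09 (SE 0.151 with the replicate block), a fold of 4.24 (95% interval 3.34 to 5.39). The 3 replicate pairs gave log2 differences of 2.19, 2.25 and 1.81. Among the Notch targets, Hes5 passed without the block (limma adjusted p = 0.0011, adjusted over the list alone). Over all probes its adjusted p was 1.00 without the block and 0.00578 with it. Within replicates 2 and 3 alone the log2 difference was 2.03 (limma adjusted p = 0.0499).

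Few probes passed the tests between genotypes. Without the block, limma placed 0 of 33012 probes past an adjusted p of 0.05. In simulated data this fit recovered 0% of 2-fold and at most 0.20% of 4-fold changes. Its lack of calls, here and below, therefore does not show that genes were unchanged. An unadjusted p under 0.05 was reached by 217 probes (0.66%), of which 114 were higher and 103 lower in the knockout. With the replicate block 2 probes passed, Nrarp (lower) and Hes5 (higher), and 1238 had an unadjusted p under 0.05 (582 higher, 656 lower). The count of 217 was not stable, at 47 with centring on 75th percentiles, 419 without wild-type replicate 1, 993 without knockout replicate 1 and 3145 with array weights. Both calls were lost when the block was combined with a variance prior that ignores the intensity level (smallest adjusted p 0.975, 0 probes). In simulated data with 0 true changes the blocked fit called at least 2 probes in 8 of 20 runs when each probe kept its own estimated spread, and in 0 of 20 when the spread was drawn from the fitted prior, so a count of 2 does not by itself exceed what chance gives.

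Besides Nrarp and Hes5, the named genes ranked highest among those with separated groups and above the median level did not pass over all probes. Rhox5, an X-linked homeobox gene, read 5.42 ± 1.75 (SD, n = 3) in wild type and 14.0 ± 1.17 (SD, n = 3) in the knockout. Car4, a membrane-bound carbonic anhydrase, read 6.48 ± 0.615 (SD, n = 3) and 14.8 ± 2.31 (SD, n = 3). The log2 differences were 1.43 for Rhox5, 1.18 for Car4, 1.67 for the troponin gene Tnnt3 and 1.69 for the agouti pigment gene. On the lower side they were -1.16 for the sialyltransferase gene St3gal1, -1.14 for Zfp459, -1.69 for the dynein chain gene Dync1i1 and -1.38 for 1700016K19Rik. Tnnt3 averaged below the array medians in wild type, at 0.530. Zfp459, Dync1i1 and 1700016K19Rik did so in the knockout, at 0.608, 0.821 and 0.625. In the blocked limma fit the adjusted p was 0.610 for Rhox5 and Car4 and 0.999 for the other 6 genes given after them.

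**Figure D1:**
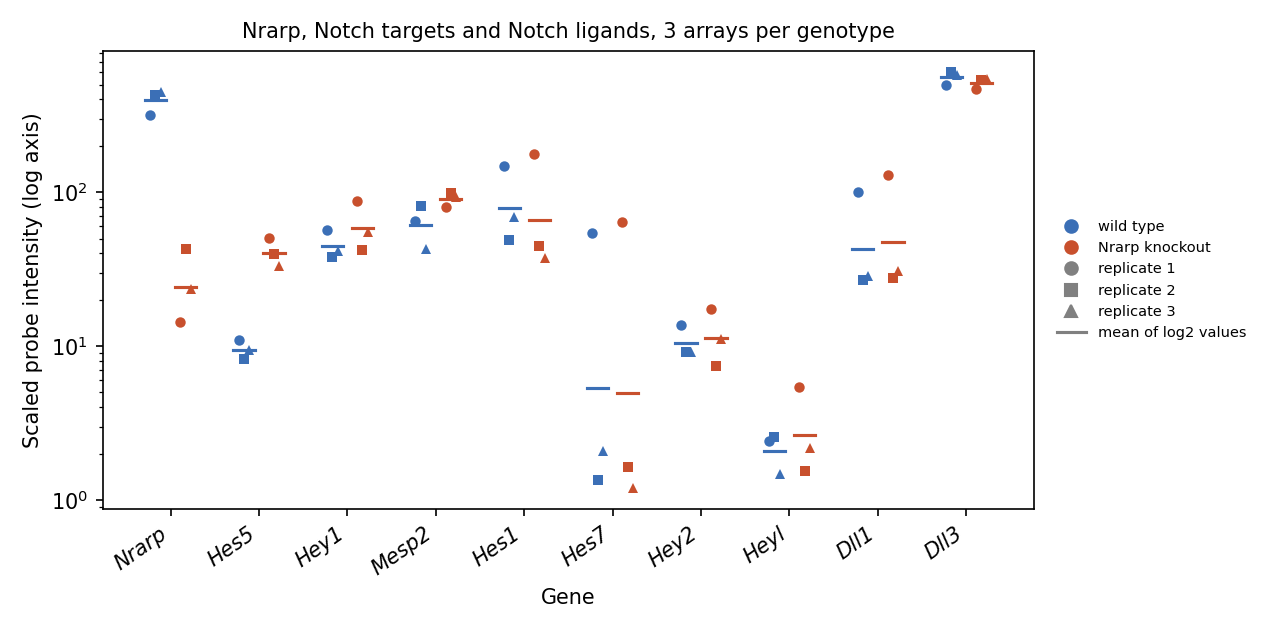
Scaled probe intensity (log axis, arbitrary units) of Nrarp, Notch targets and Notch ligands on each of the 3 wild-type (blue) and 3 Nrarp knockout (red) arrays, with symbols for the replicate number and bars for the mean of log2 values. Nrarp averages 398 in wild type and 26.7 in the knockout, and Hes5 averages 9.57 and 40.9.

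The 13 measured Notch targets were not called as a group by camera (adjusted p = 0.789 without and 0.551 with the block). Of these, 7 had a positive and 6 a negative log2 difference, with a median of 0.11 and a mean of -0.06. Without the block Nrarp fell and Hes5 rose among them, adjusted over the list alone. With the block Hey1 and Mesp2 also passed over the list alone (adjusted p = 0.042 for each in limma), and neither passed over all probes (0.999). That adjustment counts the replaced gene Nrarp as a member and was not repeated without it. In the other list that holds each gene, both missed the threshold with the block. The limma adjusted p was 0.0551 for Hey1 among the Notch and FGF cyclic genes and 0.0926 for Mesp2 among the anterior presomitic mesoderm and somite genes. Hey1, a Notch-induced repressor, read 45.3 ± 9.92 (SD, n = 3) in wild type and 61.7 ± 23.4 (SD, n = 3) in the knockout, a log2 difference of 0.40. Mesp2, which sets the anterior border of the forming somite, read 63.1 ± 19.3 (SD, n = 3) and 90.4 ± 9.44 (SD, n = 3), a log2 difference of 0.56. The other targets of this list did not pass in either fit, among them Hes1 (-0.26), the clock repressor Hes7 (-0.10), Hey2 (0.11) and Heyl (0.34). The sign of these 4 differences was not held when single arrays were left out, and it differed between replicate pairs. The largest positive difference after Hes5 was that of the dim gene Dtx1 (1.33, positive in all 3 pairs), and Efnb2 was at -0.70, negative in all 3 pairs. Over the list alone with the block their limma adjusted p was 0.0547 and 0.273. Lfng, the glycosyltransferase of the clock, has no named probe here.

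Genes that make up the Notch pathway itself did not pass. All 24 measured components missed the threshold in both fits, over all probes and over the list alone, with 14 positive and 10 negative differences and a median of 0.10. The ligand gene Dll1 differed by 0.17 and Dll3 by -0.11 on the log2 scale. Dll3 was the brightest of these genes at 559 ± 57.9 (SD, n = 3) in wild type and 516 ± 39.2 (SD, n = 3) in the knockout. Notch1 lay below the array median (0.456 ± 0.0391 in wild type, SD, n = 3) and differed by -0.20. The smallest p-values without the block belonged to the presenilin gene Psen2 (-0.35) and to Notch4 (0.51), and with it to Adam17 (0.65) and Dlk1 (0.33). Notch4 was dim, averaging 0.875 in wild type and 1.26 in the knockout. Both Dll1 and Notch1 changed sign when single arrays were left out. Dll1 was positive within all 3 replicate pairs matched by number, but it read 27.5 on knockout replicate 2 and 28.7 on wild-type replicate 3.

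Among 17 measured cyclic genes of the Notch and FGF branches, 7 had positive and 10 negative differences, with a median of -0.10. Nrarp and Hes5, which also stand in the Notch target list, passed over the list alone in both fits (adjusted p = 2.2e-04 and 0.0014 without the block in limma). With the block Snai1, a repressor of epithelial genes that oscillates in this tissue, passed over the list alone (log2 difference 0.69, limma adjusted p = 0.022). Snai1 did not pass among the 16 FGF signalling genes and targets (adjusted p = 0.063 over that list), where the differences were 8 positive and 8 negative and the median was -0.02. There Spred2 differed by 0.46, the ligand gene Fgf8 by -0.39 and the phosphatase gene Dusp6 by -0.32. No member of the Wnt lists passed. The 8 cyclic Wnt genes had a median of 0.01, with Dact1 at 1.13, Myc at 0.21 and Axin2 at -0.07. Dact1 was dim, averaging 0.819 in wild type and 1.71 in the knockout. The 17 Wnt targets and feedback genes had a median of 0.08, with Ccnd1 at 0.59, Notum at -0.72 and Lef1 at 0.30. Leaving out single arrays, which unbalances the replicates, turned the sign of Fgf8, Dusp6, Axin2 and Lef1, although Fgf8, Dusp6 and Lef1 kept 1 sign in all 3 replicate pairs.

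Markers of the posterior presomitic mesoderm and tailbud did not pass the test between genotypes. Of 21 measured members 0 passed in either fit, 7 differences were positive and 14 negative, and the median was -0.05. Tbx6, a T-box factor required for presomitic identity, read 606 ± 170 (SD, n = 3) in wild type and 712 ± 197 (SD, n = 3) in the knockout (log2 difference 0.23). Msgn1 differed by 0.15, the Wnt potentiator gene Rspo3 by -0.29 and the retinoic acid degrading enzyme gene Cyp26a1 by -0.24. Tbx6 was higher in all 3 replicate pairs (0.23, 0.19 and 0.29), although its sign turned when 1 array was left out, and Msgn1 held its sign in neither check. The T gene has no named probe here.

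In the 19 measured genes of the anterior presomitic mesoderm and somite, 10 differences were positive and 9 negative, with a median of 0.08. Aldh1a2, which makes retinoic acid in the anterior presomitic mesoderm and somites, passed over the list alone with the block (log2 difference 1.23, SE 0.217, limma adjusted p = 0.0068), but not without it (0.883). It was higher in the knockout in all 3 pairs, by 1.69, 1.37 and 0.63, but the groups overlapped. Its single arrays read 24.3, 3.57 and 5.48 in wild type against 78.5, 9.22 and 8.46 in the knockout. Aldh1a2 also differed strongly between replicates, averaging 51.4 on the replicate 1 arrays and 6.68 on those of replicates 2 and 3. Eya1 (0.93) and Tbx18 (-1.02) did not pass. Both were dim, averaging 0.311 and 1.20 in wild type and 0.590 and 0.593 in the knockout. Aldh1a2 also passed among the 12 retinoic acid pathway genes with the block (adjusted p = 0.0043 over that list), where Rdh10 (-1.51) did not pass and the median was -0.08.

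The Hox genes gave 0 calls in both fits. Of 12 measured members of paralogue groups 9 to 13, 10 had negative and 2 positive differences, with a median of -0.17, among them Hoxd9 at -0.18 and Hoxb9 at -0.33, whose signs turned when single arrays were left out, although Hoxd9 was negative in all 3 replicate pairs. The 18 measured members of groups 1 to 8 had a median of -0.04, with Hoxa6 at -1.07 and Hoxa3 at -0.85. The 7 measured axial length regulators had a median of -0.03, with Nr6a1 at 0.60 and Acvr1b at -0.56, and Gdf11 has no named probe here. Nr6a1 and Acvr1b were dim, averaging 0.387 and 0.387 in wild type and 0.550 and 0.270 in the knockout. Hoxa6 was dim too, at 0.994 in wild type and 0.647 in the knockout.

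Of the 26 lists, 0 were called by limma's camera test with a preset correlation, either without the block (smallest adjusted p 0.430, sex-linked controls) or with it (0.142, the same list). With an estimated correlation the smallest adjusted p was 0.937 without the block and 0.934 with it. The rotation test fry, which asks whether members move one way on balance, gave no call either (smallest adjusted p 0.997 without the block and 0.952 with it). Its mixed form, which asks only whether members change in either direction, gave blocked adjusted p-values of 0.0136 for Notch targets, 0.0046 for Notch and FGF cyclic genes, 0.0014 for anterior presomitic mesoderm and somite genes and 0.0154 for the genes next to Nrarp. Without the block it called Notch targets only (0.0064). Unlike the main fits and camera, fry was run without an intensity trend in its variance model. Under such a model the blocked calls of single probes were lost. The Notch target and the cyclic list both hold Nrarp, the gene that was replaced. With Nrarp left out, chosen after the result was seen, the blocked fry adjusted p was 0.0056 for Notch targets and 0.0117 for the cyclic genes, and without the block it was 0.0825 and 0.935, so that neither was called. Median, mean and camera direction were not all of the same sign for the Notch targets, FGF, axial length, neural crest, surface ectoderm, notochord and immediate early lists.

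**Figure D2:**
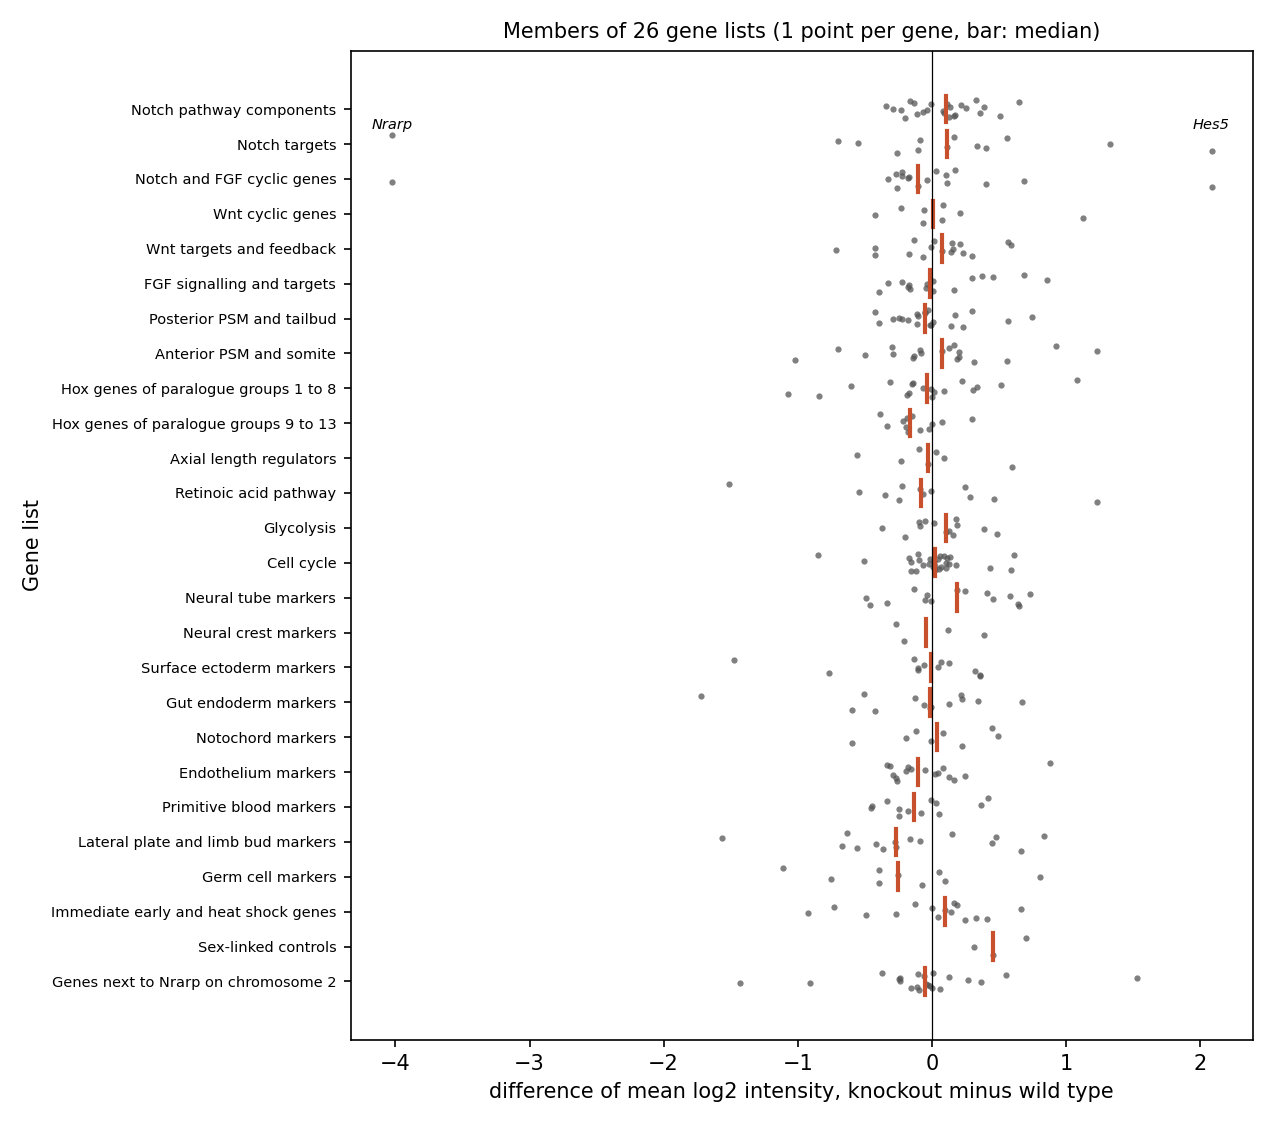
Difference of mean log2 intensity (knockout minus wild type, horizontal axis) for each measured member of the 26 gene lists (vertical axis), 1 grey point per gene and a red bar at each list's median. Nrarp at -4.03 and Hes5 at 2.09 stand apart, and the list medians lie between -0.27 (lateral plate and limb bud) and 0.46 (sex-linked controls).

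Markers of neighbouring cell types did not pass over all probes or over their own lists, with or without the block. The medians were 0.19 for 15 neural tube markers (Sox1 0.65, Neurog1 -0.49), -0.05 for 4 neural crest markers (Tfap2b 0.39, Isl1 -0.27) and -0.01 for 12 surface ectoderm markers (Krt15 -0.77, Krt14 0.36). They were -0.01 for 13 gut endoderm markers (Apoa1 -1.72, Foxa2 -0.60), 0.04 for 8 notochord markers (Sox9 0.45) and -0.10 for 16 endothelial markers (Lyve1 0.88, Tal1 -0.34). The medians of 12 primitive blood markers (Hemgn -0.33, Alas2 -0.25), 15 lateral plate and limb bud markers (Lhx9 -1.56, Pitx1 0.67) and 9 germ cell markers (Nanos3 0.81, Dnd1 -0.75) were -0.13, -0.27 and -0.25. Sox9 and Tal1 changed sign with single arrays left out, and only Sox9 kept its sign in all 3 replicate pairs matched by number. Sox9 still read 1.89 on knockout replicate 2 and 1.96 on wild-type replicate 3. Sox1, Lyve1 and Nanos3 were dim, averaging 0.375, 0.416 and 0.392 in wild type. So were Apoa1 and Lhx9 in the knockout, at 0.435 and 0.909.

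Genes of general cell state gave 0 calls as well. The 30 cell cycle genes had a median of 0.03, with Ccnd1 at 0.59 and the inhibitor gene Cdkn1b at 0.61. The 13 glycolysis genes had a median of 0.10, with Ldha at 0.18 and Hk1 at 0.48. The 15 immediate early and heat shock genes had a median of 0.10, with Egr2 at -0.93 and Zfp36 at -0.73. Cdkn1b and Egr2 were dim, averaging 0.387 and 0.520 in wild type and 0.589 and 0.267 in the knockout. All 3 measured sex-linked controls are Y-linked and had positive differences. Eif2s3y read 41.9 ± 12.2 (SD, n = 3) in wild type and 57.4 ± 17.3 (SD, n = 3) in the knockout, and passed over that list with the block (log2 difference 0.46, limma adjusted p = 0.020). Uty differed by 0.70 and did not pass, and its sign, like that of Hk1, turned with single arrays left out. Of 22 measured genes next to Nrarp on chromosome 2, 8 had positive and 14 negative differences with a median of -0.05, and 0 passed. Cysrt1, a dim probe at 0.983 ± 0.0366 (SD, n = 3) in wild type and 0.364 ± 0.0090 (SD, n = 3) in the knockout, differed by -1.43, and Abca2 by 1.53.

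The largest difference between arrays did not follow genotype. Replicate 1 of wild type and replicate 1 of the knockout resembled each other and stood apart from replicates 2 and 3 of both genotypes. Across all probes Spearman's rho was 0.930 between the replicate 1 arrays and 0.792 to 0.837 for every other pair of arrays, a description across genes, which are not independent replicates. Between the replicate 1 arrays and the other 4 arrays, adjusting for genotype, limma found 12155 probes past an adjusted p of 0.05, of which 5723 were higher and 6432 lower in replicates 2 and 3. This division of arrays was chosen after the values were seen, and all genes named for it are from the lists. Hes7 averaged 59.2 on the 2 replicate 1 arrays and 1.57 on the other 4 (log2 difference -5.27, limma adjusted p = 7.5e-06). Msgn1 averaged 50.2 and 3.47, Wnt5a 66.0 and 7.61, Axin2 6.45 and 0.531, and Dll1 115 and 28.4. Tbx6 went the other way, at 451 and 763. Both genotypes were represented on each side of this division, and Nrarp and Hes5 kept their directions within replicate 1 and within replicates 2 and 3.

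**Figure D3:**
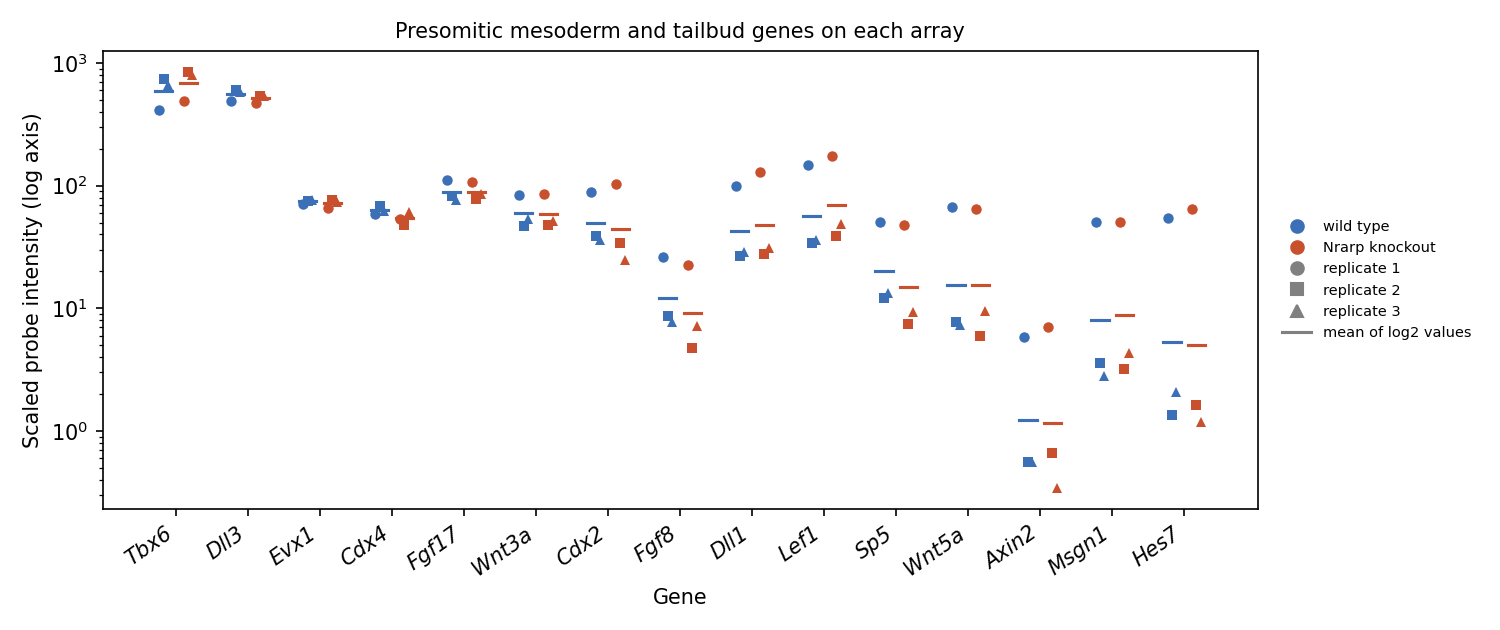
Scaled probe intensity (log axis, arbitrary units) of 15 presomitic mesoderm and tailbud genes on each wild-type (blue) and Nrarp knockout (red) array, with symbols for the replicate number and bars for the mean of log2 values. Circles (replicate 1) lie far above squares and triangles for Hes7 (59.2 against 1.57 on average) and Msgn1 (50.2 against 3.47), and below them for Tbx6 (451 against 763).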

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

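The batch term for replicate 1, the fits on replicates 2 and 3 alone, mixed fry with the block or without Nrarp, and the combinations of the replicate block with another choice were chosen after the data were seen. Of 33 settings, 27 refitted single genes and the others changed only a threshold or the list test. Over those 27, 1935 of 1991 values for 75 named genes other than Nrarp kept direction and side of the threshold. Of the remaining values 9 (all Hes5) moved past it, 0 moved back and 47 changed sign without being called. The count of probes past the threshold was 0 in most settings. It was 217 at an unadjusted p with at least 1.5-fold, 1 with array weights, 2 with the replicate block, 2 with the batch term, 2 on replicates 2 and 3 alone, 2 with the block and quantile normalization, an offset or the brighter probes only, and 0 with the block and no intensity trend. Over all probes, and for whole lists by camera and directional fry, the block changed no other call, and over single lists it added Hey1, Mesp2, Snai1, Aldh1a2 and Eif2s3y. Of these, Hey1, Mesp2 and Snai1 each passed in 1 list and missed the threshold in the other list that holds them. In mixed fry the block added the Notch and FGF cyclic genes (adjusted p 0.165 to 0.0046), the anterior presomitic and somite genes (0.935 to 0.0014) and the genes next to Nrarp (0.935 to 0.0154). With Nrarp left out, mixed fry called the Notch targets with the block only (0.0056 against 0.0825), and the same held for the cyclic genes (0.0117 against 0.935). With the block and pair 1, 2 or 3 left out, 2, 2 and 7 probes passed, the last including 5 unnamed probes. Nrarp passed at -4.10 with array weights, -4.03 with the replicate block or the batch term, -3.80 on replicates 2 and 3, and, with the block, at -4.15 (quantile), -4.01 (offset), -4.03 (brighter probes), and -3.80, -4.37 and -3.91 with pairs 1, 2 and 3 left out. The number of lists called by camera was 0 except with the block and pair 2 left out, where 2 were called, primitive blood markers down (adjusted p = 7.0e-05) and sex-linked controls up (0.010). The cause was not tested. Hes5 passed over the Notch target list alone in 27 of 27 settings where this was computed (limma adjusted p 4.43e-07 to 0.00967), at 1.93 to 2.22.

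Sign changes occurred in 18 uncalled genes, and the cause was not tested. Of these, Tbx6, Fgf8, Dusp6, Hoxd9, Dll1, Lef1 and Sox9 had 1 sign in all 3 replicate pairs matched by number. With replicates 2 and 3 matched across numbers, Dll1 and Sox9 did not keep it, and the others of this group did. On replicates 2 and 3 alone, and with the block and pair 1 left out, Hey2 was -0.0010, Heyl -0.083 and Notch1 0.28. With the block, Hoxb9 was 0.16 with pair 2 left out, and with pair 3 left out Hes1 was 0.065, Hes7 0.25, Axin2 0.25, Msgn1 -0.090 and Uty -0.18. Leaving out each array in turn, which can unbalance the groups against the replicate 1 arrays, gave ranges of -0.97 to 0.19 for Hes1, -1.94 to 1.57 for Hes7, -1.36 to 1.07 for Axin2, -0.017 to 0.49 for Tbx6, -1.04 to 0.16 for Fgf8, -0.85 to 0.056 for Dusp6 and -0.38 to 0.047 for Hoxd9. They were -1.24 to 0.23 for Hoxb9, -0.55 to 0.79 for Dll1, -0.37 to 1.00 for Lef1, -1.11 to 1.47 for Msgn1, -0.34 to 1.40 for Hk1 and -0.049 to 1.20 for Uty. They were -0.20 to 0.41 for Hey2, -0.19 to 0.72 for Heyl, -0.69 to 0.24 for Notch1, -0.085 to 1.03 for Sox9 and -0.61 to 0.032 for Tal1.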

Other observations

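The tests of Hes5 against neural tissue, the replicate 1 arrays and other Notch targets, the test of a smaller share of presomitic mesoderm with its cell type markers, the count of probes after quantile normalization, and the splits of the probe count without the block were chosen after the result was seen. Genes with the smallest p in the blocked fit that did not pass over all probes, named after their values were seen, include Fabp7, a fatty acid binding protein of neural progenitors, at 217 ± 32.6 (SD, n = 3) in wild type and 330 ± 34.2 (SD, n = 3) in the knockout. Pcp4, a calmodulin-binding peptide gene, read 67.2 ± 7.92 (SD, n = 3) and 108 ± 7.43 (SD, n = 3). Gadd45g, a stress and cell cycle gene, differed by 0.59 on the log2 scale, Trap1a by 1.18, Xlr3c by 0.64 and Lor, an epidermal envelope gene, by 0.78. On the lower side were Zbtb7c (-0.61), the forkhead gene Foxd1 (-0.54) and the orphan nuclear receptor gene Nr4a3 (-0.63). The blocked limma adjusted p was 0.889 for Fabp7 and 0.999 for the other genes named here.

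Hes5 was higher in the knockout while most other Notch targets were not called. Neural tube tissue in the knockout samples is argued against: 7 neural tube markers above the median level had a median log2 difference of -0.033 (bootstrap interval over genes -0.46 to 0.24), with Tubb3 at -0.03 and Sox2 at -0.46, although Fabp7 (0.61), Irx3 (0.41) and Stmn2 (0.24) were positive without passing. The difference did not rest on the replicate 1 arrays alone, at 2.19 within replicate 1 and 2.03 within replicates 2 and 3 (95% interval 1.56 to 2.50). This check adds little, because replicate 1 holds 1 array of each genotype and a shift shared by both could not produce a difference. The blocked fit that called Hes5 also favours genes whose difference agrees over the replicates. Whether most Notch targets are slightly higher stays open, because the other 11 targets had a median of 0.11, 6 of them above 0. An effect of the knockout and a change in a minor cell type not covered by the marker lists stay open and untested.

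Replicate 1 of both genotypes stood apart from replicates 2 and 3, and the cause is not in the labels. Dim probes are argued against as the whole source: among the 3302 brightest probes the SD of log2 differences across this division was 3.57 times that within replicates 2 and 3. Array-wide scaling is argued against only as the whole source, because 8796 probes still differed after quantile normalization, which gives all arrays the same distribution. Of these, 4554 were higher and 4242 lower in replicates 2 and 3, a balance that the normalization partly forces and that carries no weight. The matching SD ratio of 1.74 fell between the bounds of 1.5 and 2 set beforehand, so that test left the question undecided. Whether replicates 2 and 3 held a smaller share of presomitic mesoderm stays open. Of 20 posterior presomitic and tailbud genes 1 was higher there and 13 lower as deposited, and 4 and 10 after quantile normalization, which alone does not decide it. Of 63 markers of other cell types 13 were higher there and 28 lower as deposited (20 and 20 after quantile normalization). These pooled counts cannot decide it either, because a smaller share may be made up by 1 neighbouring tissue, whose markers alone need rise. As deposited, the median was 0.87 (bootstrap interval -1.34 to 1.21) for 7 neural tube markers and -1.70 (-1.86 to 0.47) for 13 endothelial markers. The primitive blood gene Hba-x, at 1445 on replicate 1 and 3472 on the others, was the 1 marker of its list called higher as deposited, against 5 called lower. A different batch of RNA preparation, labelling or arrays, or a difference in dissection or clock phase of the embryos, may underlie the division and was not tested; Hes7, the clock gene, differed most of the genes named for it.

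Rhox5, Trap1a and Xlr3c, X-linked genes picked from those with the smallest p in the blocked fit, had positive differences, but none passed over all probes (limma adjusted p 0.610, 0.999 and 0.999) and the groups overlapped for Trap1a, so the pattern itself is not established. Extraembryonic tissue of the kinds covered by 5 markers above the median level, of 9 measured, is argued against by their median of -0.24 (interval -0.62 to 0.21), although these markers were dim (wild-type means 1.28 to 5.77) and the trophoblast gene Tpbpa, below that level, was at 0.95 (SE 0.60). A larger share of males in the knockout stays open. X-linked genes above the median level had a median log2 difference of -0.032, against -0.0064 for autosomal genes. The interval of -0.055 to -0.0088, like that above, is a bootstrap over genes and does not measure the spread between samples. The bound of 0.5 set beforehand was wrong, because X inactivation evens most X-linked genes between the sexes. All 3 Y-linked controls were positive over the 6 arrays, Eif2s3y by 0.46 (limma adjusted p = 0.020 over its list with the block). Within replicate pair 2, however, Uty was at -0.68 and the median of the 3 at -0.035, with Eif2s3y at 0.21. A difference in strain background between the genotypes may contribute, as may a biological effect of the knockout, and neither was tested. The labels do not give the strain, but they call the wild-type embryos littermates, which would limit such a difference. The agouti gene was 3.22-fold higher in the knockout without passing. It was low on the arrays, at 1.14 ± 0.528 (SD, n = 3) in wild type and 3.48 ± 0.939 (SD, n = 3) in the knockout, and is no evidence on strain.

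Of the 10 splits of the 6 arrays into 3 and 3, all 10 gave as many probes as the real split without the block (0 real, 0 at most in the others) and all 10 gave as many lists (0 real, 5 at most in the others). With 0 in the real split every split reaches it by construction, so these counts say nothing about chance. Among the 4 splits that part all 3 replicate pairs, 1 gave as many probes with the block, the real one (2 real, 0 at most in the others). These splits are too few for a share under 0.05, and in simulated data without true changes the blocked fit also reached 2 probes, in 8 of 20 runs with each probe's own spread. Splits that put both replicate 1 arrays on the same side gave 3800 to 7225 probes at an unadjusted p under 0.05, against 217 for the real split, which points to the structure of the arrays. The other splits that part the replicate 1 arrays gave 207 to 238 without the block. With the block, the other splits that part all pairs gave 1173 to 1992, against 1238 for the real split, so neither count of the real split stands out.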
